A study of Mus musculus with 12 samples.

How the data were processed

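T cell receptor clonotype tables of 12 libraries were used, 24 files in all, 1 of alpha and delta chains (TRA and TRD) and 1 of beta chains (TRB) for each library. Thymocytes were stained for CD4 and CD8 and sorted, RNA was extracted, and libraries were made with the SMARTer mouse TCR kit and sequenced on a MiSeq instrument, per the labels. The series design text names MiXCR for clonotype assembly and VDJtools, Prism 5.0 and a paired two-tailed comparison for the statistics, and the genome build mm10 comes from the submitters' processing notes. The MiXCR version, the quality filters and the alignment parameters were not given in the sources used here. The deposited values are counts of reads per clonotype, which are whole numbers whose totals differ between libraries, per the file headers. The deposited fraction of each clonotype is its read count divided by the file's total, and was used only to check the counts. The files hold no column of molecule counts, so amplification of single molecules could not be removed, and intervals and floors cover counting error only.

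From each file, productive clonotypes were kept, that is, those whose CDR3 (the loop formed where V and J segments join) was covered and had neither a frame shift nor a stop codon. Clonotypes with a TRDV or TRDJ best hit were kept out of the TRA tables and counted apart. Reads without a covered CDR3 were 1.96% to 3.15% of the TRA and TRD reads of a library and 0.513% to 0.837% of its TRB reads. Out-of-frame or stop reads were 7.24% to 8.28% of the rest for TRA and 1.36% to 2.33% for TRB. Segments were taken from the best hit with the allele dropped. In TRA, 30.4% to 44.2% of productive reads had a second segment with the same score, since many mouse TRAV segments have near-identical copies, so values of single TRAV copies are uncertain. Segment positions came from the RefSeq gene table of the same build, in which 179 of 179 segments were matched.

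Reads of productive clonotypes were summed per V and J segment, per residue and offset from the middle of the CDR3 (up to 2 residues on each side), and per amino acid clonotype found often enough to test. Each table was tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test. The library size was the productive reads of the chain without further scaling, features were kept by filterByExpr with the groups, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Genotype contrasts were fitted on all 12 libraries, so that the groups shared 1 estimate of the spread, with the replicate number as a block because the design text names pairs of mice. These fits took the CD4SP and CD8SP libraries of a mouse as independent, although their segment usage deviated together, so their p-values may be inexact. CD4SP against CD8SP, and the test of whether genotype effects differed between them, had the mouse as a block. The 10 lists of segments were fixed in advance; 9 with at least 3 members were tested with fry in limma 3.58.1, which asks whether a list changed at all. camera, with an estimated correlation, asked a different question, whether a list changed more than the other segments, so a call lost with it can come from either difference. A panel of 27 measures per library was compared by exact two-sided permutation tests, flipping signs within pairs or mice and permuting labels without pairs. Diversity measures used 20 draws of 19847 TRA or 74021 TRB productive reads, the size of the smallest library, and sharing of TRA clonotypes between libraries was counted without the invariant chain at 18551 reads. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

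The scripts' tests were checked on simulated counts drawn with each feature's mean over all 12 libraries and the real library sizes, in which 20% of features were changed. For TRA segments in CD4SP, 44.4% of segments changed 1.25-fold (4 of 9) and 87.5% of those changed 2-fold (7 of 8) were recovered. All TRB segments so changed were recovered in that contrast, but these were only 3 at 1.25-fold and 2 at 2-fold. The simulated counts had 1 common spread for all features of a table, no level of the mouse and, in the genotype contrasts, no difference between CD4SP and CD8SP. Recovery of single segments in the real data can therefore be lower. Of the public clonotypes, 0% were recovered at a 2-fold change between genotypes, so those tests had little power for a change of that size. Chains abundant in 1 cell type only, such as the invariant chain, were not simulated at their level there, so this need not hold for them.

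The segments and clonotypes named in the text were chosen by a rule. It took segments past the threshold, at most the 10 largest changes per direction and chain among those with a mean share of at least 0.1%, and the 5 with the smallest p where fewer than 5 passed. It added each member of the superantigen list and of the TRBV13 family, up to 5 residues per direction, cysteine, and up to 3 public clonotypes per direction. The groups, tests, lists, naming rule and most alternatives were set before the data were examined. The alternatives were each clonotype counted once, TMM factors, DESeq2 1.42.0 with its size factors, no filter on low features, clonotypes with 1 read left out, only the libraries of the contrast, no replicate block, clonotypes with tied segments left out, amino acid clonotypes, fewer reads per draw, the methods' paired test, camera, and each library or mouse left out in turn. Leaving out the invariant chain, merging TRAV copies, adding TRDV segments and summing the beta chains that pair with the invariant chain were chosen after seeing the data. The sequences of TRD clonotypes, and the V segment sequences outside the CDR3 beyond 1 check for alleles, were not analysed here.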

Results

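T cell receptor (TCR) repertoires were measured in thymocytes of wild-type (WT) mice and of mice lacking Chrna9, the gene of the alpha 9 subunit of nicotinic acetylcholine receptors (mm10, chromosome 5, 65934854 to 65977486). The series title concerns negative selection, the removal of thymocytes with strongly self-reactive receptors, and the genotype comparison asks whether loss of Chrna9 changed the receptors that maturing thymocytes carry. CD4 single-positive (CD4SP) and CD8 single-positive (CD8SP) thymocytes, which follow selection on MHC class II and class I, were sorted by CD4 and CD8 alone. That gate can hold invariant natural killer T (NKT) cells and mucosal-associated invariant T (MAIT) cells, so their receptors were counted as markers. It can also hold immature single-positive and double-positive cells, which have no TCR gene marker. Their number was not measured, so differences between CD4SP and CD8SP cannot be assigned to mature cells alone. The 4 groups held 3 libraries each, from 6 mice in 2 male pairs and 1 female pair, with 1000000 sorted cells per CD4SP sample and 330000 per CD8SP sample. Productive TRA reads per library numbered 19847 to 24605 in WT CD4SP, 23765 to 30831 in knockout CD4SP, 23402 to 33885 in WT CD8SP and 31205 to 33285 in knockout CD8SP. Productive TRB reads numbered 74021 to 86935, 80040 to 104434, 92648 to 134169 and 118507 to 119381 in the same order. These reads formed 10456 to 14981 TRA and 36741 to 51904 TRB nucleotide clonotypes per library. TCR libraries hold no readout of Chrna9, so the knockout was not checked here.

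In CD4SP thymocytes, knockout libraries held more reads of the invariant NKT alpha chain, the 15-residue join of TRAV11 and TRAJ18 with which NKT cells recognise lipids on CD1d. TRAV11 (chromosome 14, 53519303 to 53519859) rose by a log2 fold change of 0.25 (SE 0.057), from 6.75% ± 0.682 to 8.02% ± 1.04 of productive TRA reads (SD, n = 3 in each group). TRAJ18 (chromosome 14, 54200777 to 54200842) rose by 0.23 (SE 0.053), from 8.07% ± 0.870 to 9.47% ± 1.00, and both were higher in 3 of 3 pairs. The invariant chain itself made up 7.39% ± 1.06 of knockout and 6.03% ± 0.677 of WT reads. In CD8SP it made up 0.0601% ± 0.0124 and 0.0708% ± 0.0241. The pair difference in CD4SP was 1.35 ± 0.530 percentage points (SD over 3 pairs), with an exact two-sided sign-flip permutation p = 0.25, the smallest that 3 pairs allow. A permutation of labels without pairs gave p = 0.2, where 0.1 is the smallest 3 libraries against 3 can give. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called TRAV11 and TRAJ18 among 125 TRA segments (adjusted p = 0.00119 for each), 0 segments lower, and 7 segments at an unadjusted p under 0.05. DESeq2 called 1 segment, TRAV11 (adjusted p = 0.029), with 7 at an unadjusted p under 0.05. The segments of next smallest p did not pass in edgeR's main fit: TRAJ23 at -0.16 (adjusted p = 0.169), TRAV12-2 at -0.63 and TRAV13-2 at -0.37 (adjusted p = 0.315 for both). TRAV12-2 passed without clonotypes of 1 read (-1.25, adjusted p = 0.0408) and TRAV13-2 without WT replicate 2 (-0.54, adjusted p = 0.0378). The calls of TRAV11 and TRAJ18 ended without the replicate block (adjusted p = 0.0822 for each) and without WT replicate 1 (0.0565 and 0.441), WT replicate 3 (0.154 and 0.137) or knockout replicate 3 (0.229 and 0.588). With each clonotype counted once TRAV11 was at -0.13 and TRAJ18 at -0.02, without the invariant chain they were at -0.16 and 0.05, and without tied segments TRAJ18 was at 0.07 with TRAV11 removed, none of them past the threshold. These settings take away the read abundance of the invariant chain or the chain itself. They show that the calls rest on that abundance, not whether it differs between genotypes.

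**Figure D1:**
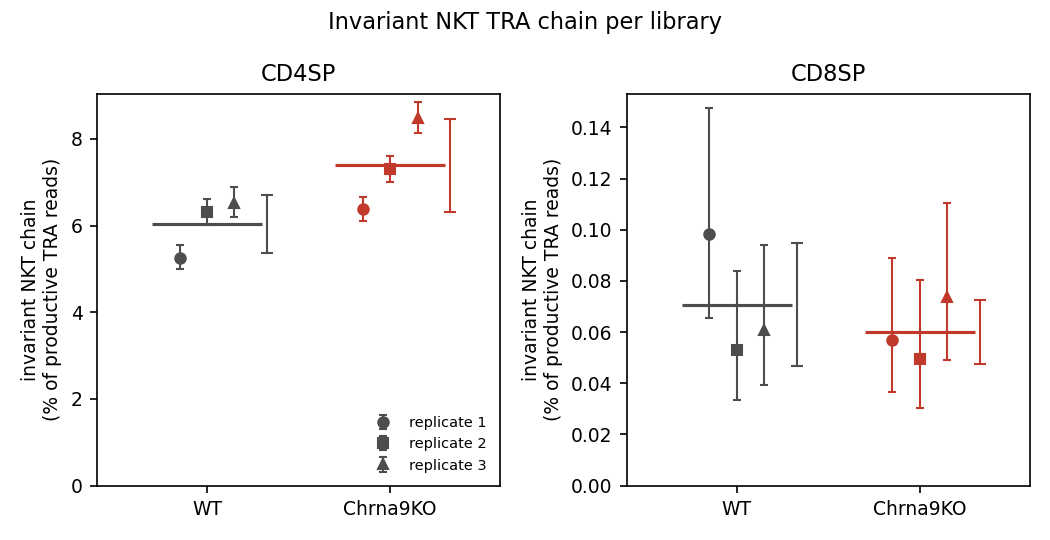
Share of productive TRA reads (%) that were the invariant NKT chain, in CD4SP and CD8SP libraries on separate axes, with points for the 3 replicates of each genotype, bars for 95% Wilson intervals (counting error only), a line for the mean and a side bar for the SD. CD4SP libraries lay between 5.26% and 6.53% in WT and between 6.37% and 8.49% in the knockout.

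Residues at the middle of the TRA CDR3, the part of the loop that lies over the bound peptide or lipid, also differed between genotypes in CD4SP. Leucine 2 residues after the middle rose by a log2 fold change of 0.24 (SE 0.048), from 8.41% ± 0.847 to 9.98% ± 1.16 (n = 3). Arginine 2 residues before the middle (0.13), glycine 1 residue before it (0.09), serine at the middle (0.09) and alanine 1 residue after it (0.10) also rose, and asparagine 2 residues before it fell by 0.14. Arginine, glycine, serine, alanine and leucine are, in that order, the middle of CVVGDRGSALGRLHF, the invariant chain with the most reads. Cysteine, which is enriched at the middle of strongly self-reactive receptors, was at -0.52 (SE 0.491, adjusted p = 0.755) 1 residue before the middle and at 0.13 (SE 0.417, adjusted p = 0.874) 2 residues before it in edgeR's test. TRA CDR3s with cysteine within 2 residues of the middle made up 0.118% ± 0.0221 of knockout and 0.1205% ± 0.0444 of WT reads. edgeR called 6 of 94 residues, with adjusted p from 0.000535 (leucine) to 0.0275 (asparagine) and 12 at an unadjusted p under 0.05, and DESeq2 called 0, with 7 at an unadjusted p under 0.05. Counting each clonotype once or leaving out the invariant chain left 0 calls, with alanine at -0.02 in both. Without that chain arginine was at 0.03, glycine at 0.03, serine at 0.04, leucine at 0.14 and asparagine at -0.12 (edgeR adjusted p from 0.337 to 0.804). Leaving out clonotypes with 1 read or WT replicate 1 left 1 call, and leaving out knockout replicate 3 left 2.

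Beta chain segments were at similar levels in knockout and WT CD4SP. The superantigen list, which need not be complete, held 7 TRBV segments that bind endogenous superantigens (TRBV12-1, TRBV12-2, TRBV15, TRBV16, TRBV17, TRBV26 and TRBV29). Carriers of such segments are deleted in the thymus of strains that express these superantigens. The 7 segments made up 20.3% ± 0.145 of knockout and 20.4% ± 0.260 of WT reads (SD, n = 3). Of them 0 passed, and 0 when adjusted over the list alone, with log2 fold changes from -0.08 (TRBV26) to 0.08 (TRBV15). The TRBV13 family, a large group of mouse beta chains, made up 25.8% ± 0.143 and 25.7% ± 0.412, with 0 of 3 members past the threshold and TRBV13-2, the main partner of the invariant chain, at 4.07% ± 0.0588 and 4.04% ± 0.185. edgeR called 0 of 35 TRB segments, with 1 at an unadjusted p under 0.05, and DESeq2 called 0, with 0 at an unadjusted p under 0.05. That segment was TRBJ2-7 at -0.05 (SE 0.013, adjusted p = 0.0645), with 21.8% ± 0.06001 against 22.5% ± 0.447 and lower knockout values in 3 of 3 pairs. TRBJ2-7 passed without clonotypes of 1 read (adjusted p = 0.0187), with only the 6 CD4SP libraries (0.00432), without WT replicate 3 (0.0333) and without knockout replicate 3 (0.0431). In the TRB CDR3, 0 of 100 residues passed in edgeR (4 at an unadjusted p under 0.05) and 0 in DESeq2 (4), and 1 passed without WT replicate 1 or with each clonotype counted once.

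The lists of alpha chain segments did not pass in CD4SP either, where the lowest adjusted p of 9 lists was 0.933 by fry. J segments at the 3' end of the locus (TRAJ1 to TRAJ21), which are reached by later rounds of rearrangement, made up 40.7% ± 1.47 of knockout and 38.7% ± 0.888 of WT reads, and 1 of 14 members, TRAJ18, rose, also when adjusted over the list alone. The 5' J segments (TRAJ42 to TRAJ61), used in early rounds, made up 13.97% ± 0.722 and 14.5% ± 0.674. The list of TRAV16 to TRAV21 segments made up 6.74% ± 0.377 and 6.86% ± 0.388. The TRAV14 family made up 13.6% in both genotypes, TRAV4 3.41% and 3.37%, TRAV12 2.09% and 2.05%, TRAV9 0.162% and 0.185%, and TRAV1 with TRAV2, the V segments farthest from the J segments, 0.663% and 0.711%. In these lists 0 members passed, over all segments or adjusted over the list alone. Of public clonotypes, those shared by enough libraries to test, 0 of 286 TRA and 0 of 203 TRB passed in edgeR (6 and 4 at an unadjusted p under 0.05). DESeq2 called 1 TRA clonotype, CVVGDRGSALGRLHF, and 0 TRB (12 and 4 at an unadjusted p under 0.05), and leaving out knockout replicate 2 gave 1 TRA call in edgeR.

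Of the 27 repertoire measures, 13 went one way in 3 of 3 CD4SP pairs, 8 higher and 5 lower in the knockout, where chance gives 6.75 on average. The measures are not independent, so how far chance can move that count is not known. TRA diversity by inverse Simpson index, which weighs large clones, was 667 ± 184 in the knockout and 956 ± 186 in WT, lower in 3 of 3 pairs. The index mostly followed the invariant chain, since without that chain it was 6612 ± 267 and 6217 ± 372, higher in 3 of 3 pairs. Distinct TRA clonotypes were 11337 ± 317 and 10920 ± 412 (SD, n = 3, at 19847 reads). The MAIT chain, the join of TRAV1 and TRAJ33 that sees vitamin B metabolites on MR1, made up 0.0107% ± 0.00669 and 0.0244% ± 0.00415, from only 5, 1 and 3 reads per knockout library and 6, 7 and 4 per WT library. TRD reads made up 0.856% ± 0.0509 of all TRA and TRD reads in the knockout and 1.03% ± 0.0108 in WT. Hydropathy of CDR3 residues 6 and 7, higher where they are more hydrophobic, was -1.398 ± 0.0161 and -1.403 ± 0.00941 for TRA. For TRB it was -1.168 ± 0.0125 and -1.155 ± 0.0154, lower in the knockout in 3 of 3 pairs. In 4 measures the groups did not overlap, which chance gives in 10% of measures for 3 libraries against 3. By exact sign-flip permutation the lowest adjusted p was 0.519, and 3 pairs cannot give an unadjusted p under 0.25. The methods' paired test gave 6 measures at an unadjusted p under 0.05 and 0 after adjustment.

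In CD8SP thymocytes, no TRA or TRB segment passed between knockout and WT. TRBV segments of the superantigen list made up 38.1% ± 0.675 of knockout and 38.4% ± 1.02 of WT reads (SD, n = 3), with 0 of 7 past the threshold and TRBV16 highest at 0.17 (SE 0.083, edgeR adjusted p = 0.584). The TRBV13 family made up 29.1% ± 0.385 and 28.5% ± 0.539, with 0 of 3 past it. The TRA segment of smallest p was TRAV14D-1 at 0.25 (SE 0.076, adjusted p = 0.167 in edgeR), at 2.13% ± 0.171 against 1.79% ± 0.0948 and higher in 3 of 3 pairs. It passed with TMM factors (0.28, adjusted p = 0.0383) and was the 1 member of 7 TRAV14 segments called when adjusted over the list alone. That family had an unadjusted fry p = 0.0204 (adjusted p = 0.184, and adjusted p = 0.315 with an estimated correlation), and 0 lists passed. edgeR called 0 of 125 TRA segments (6 at an unadjusted p under 0.05) and 0 of 35 TRB segments (1), and DESeq2 called 0 of each (4 and 2). Without WT replicate 2, edgeR called TRBV16 and TRBV4 higher (adjusted p = 0.000507 and 0.012) and TRBV5 lower (0.0268).

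Residues and public clonotypes gave 0 edgeR calls in CD8SP. TRA cysteine was at -0.63 (SE 0.349, edgeR adjusted p = 0.635) 2 residues before the middle and at 0.36 (SE 0.552, adjusted p = 0.969) 1 before. TRB cysteine ran from -0.16 at the middle to 0.57 at 1 residue after it (edgeR adjusted p from 0.705 to 0.958). At an unadjusted p under 0.05 there were 5 of 94 TRA residues, 6 of 100 TRB residues, 3 of 286 TRA and 10 of 203 TRB public clonotypes, and DESeq2 called 0 of each (3, 7, 11 and 11 unadjusted). Without clonotypes of 1 read, 1 TRB public clonotype passed. Of the 27 measures, 7 went one way in 3 of 3 pairs, 1 higher and 6 lower, where chance gives 6.75, and the lowest adjusted p by exact sign-flip permutation was 0.964. TRD reads made up 0.757% ± 0.0774 of knockout and 0.999% ± 0.152 of WT reads, lower in 3 of 3 pairs (exact label permutation p = 0.1). CDR3s with cysteine within 2 residues of the middle made up 0.0955% ± 0.0319 of knockout and 0.116% ± 0.0336 of WT TRA reads. For TRB they made up 0.163% ± 0.00949 and 0.140% ± 0.0306. Hydropathy of residues 6 and 7 was -1.242 ± 0.00506 and -1.241 ± 0.0205 for TRA. For TRB it was -1.146 ± 0.0200 and -1.159 ± 0.00962. In 4 measures the groups did not overlap, again against a chance share of 10%, and the methods' paired test gave 0 measures at an unadjusted p under 0.05.

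Whether genotype effects differed between CD4SP and CD8SP was tested directly. TRAV11 had the smallest p, with a knockout effect larger in CD4SP by 0.32 on the log2 scale (SE 0.079, edgeR adjusted p = 0.256). edgeR called 0 of 125 TRA segments (2 at an unadjusted p under 0.05) and 0 of 35 TRB segments (0 unadjusted), DESeq2 called 0 of each (1 and 1 unadjusted), and the lowest adjusted p of the lists was 0.312. For the invariant chain share the difference of differences was 1.36 ± 0.513 percentage points (exact sign-flip permutation p = 0.25, n = 3 pairs). Without WT mouse 2, TRBV16 and TRBV4 were called lower (adjusted p = 0.0498 for both).

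CD4SP and CD8SP thymocytes of the same mice differed widely in segment usage. TRBV31 made up 21.5% ± 0.427 of CD4SP and 5.57% ± 0.144 of CD8SP reads (SD, n = 6 mice, log2 fold change 1.95, SE 0.014), and TRBV5 17.7% ± 0.526 and 10.3% ± 0.533 (0.78, SE 0.028). TRBV2 (1.73), TRBV23 (0.72) and TRBV3 (0.62) were also higher in CD4SP. TRBV14 was lower in CD4SP, at 2.24% ± 0.0869 against 7.76% ± 0.274 (-1.80, SE 0.032). Among alpha chains, TRAV11 (3.01), TRAJ18 (2.27), TRAV4D-4 (2.18), TRAV14D-3-DV8 (1.85) and TRAV4-2 (1.84) were higher in CD4SP, and TRAV16N was lower, at 3.59% ± 0.195 against 11.1% ± 0.361 (-1.63, SE 0.036). TRAV16D-DV11 (-1.74), TRAJ45 (-1.55) and TRAV12-1 (-1.51) were lower as well. edgeR called 98 of 125 TRA segments (44 higher and 54 lower in CD4SP) and 30 of 35 TRB segments (18 and 12). DESeq2 called 47 and 48 of the TRA segments and 14 and 16 of the TRB segments, with the median TRB segment moved by -0.16 by its scaling. TRAV11 turned to -0.06 (adjusted p = 0.463) with each clonotype counted once and to -0.23 (adjusted p = 0.0144) without the invariant chain, and TRAJ18 was at 0.34 without it. Both settings take away the read abundance of that chain. That chain made up 6.71% ± 1.09 of CD4SP and 0.0654% ± 0.0181 of CD8SP reads.

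**Figure D2:**
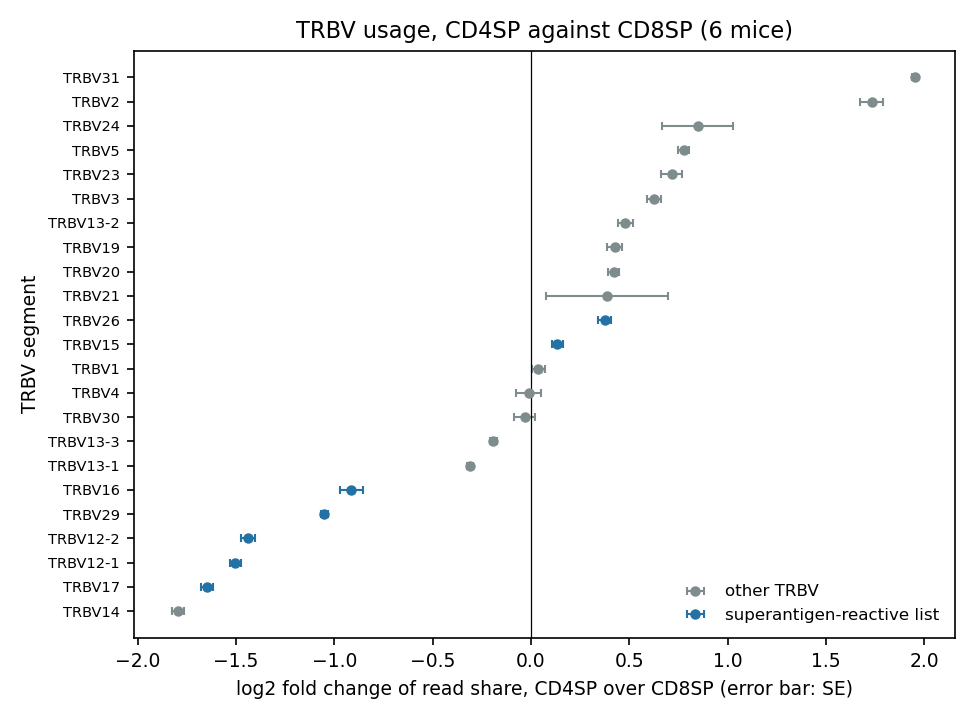
Log2 fold change of each TRBV segment, CD4SP over CD8SP, as points with SE bars from edgeR over 6 mice, with the segments of the superantigen list in blue. TRBV31 was highest at 1.95 and TRBV14 lowest at -1.80, and TRBV15 (0.13) turned to -0.03 with DESeq2's scaling.

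Segments of the superantigen list made up 20.4% ± 0.189 of CD4SP and 38.2% ± 0.787 of CD8SP TRB reads (SD, n = 6). TRBV17 (-1.65), TRBV12-1 (-1.50), TRBV12-2 (-1.44), TRBV29 (-1.05) and TRBV16 (-0.91) were lower in CD4SP, and TRBV26 (0.37) and TRBV15 (0.13) were higher, the same 5 and 2 when adjusted over the list alone. TRBV15 was at 0.00 with TMM factors and at -0.03 with DESeq2. The TRBV13 family made up 25.7% ± 0.283 and 28.8% ± 0.525, with TRBV13-1 (-0.31) and TRBV13-3 (-0.19) lower and TRBV13-2 (0.48) higher. By fry the superantigen list was lower (adjusted p = 1.77e-07) and so was the TRBV13 family (adjusted p = 0.000104). With camera, which compares a list with the other segments, neither passed (adjusted p = 0.226 and adjusted p = 0.663 with an estimated correlation). The strain of the mice, which sets which superantigens are present, was not given in the sources used here.

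Families of alpha chain segments differed between CD4SP and CD8SP in both directions. The TRAV14 family made up 13.6% ± 0.280 of CD4SP and 8.91% ± 0.525 of CD8SP reads, with 7 of 7 members higher, and the TRAV4 family 3.39% ± 0.0998 and 1.52% ± 0.227, with 3 of 5 higher and 0 lower. The TRAV16 to TRAV21 list made up 6.80% ± 0.348 and 15.8% ± 0.342, with 3 of 6 lower (4 adjusted over the list alone) and 2 higher. Most of its reads came from TRAV16N (3.59% and 11.1%) and TRAV16D-DV11 (0.724% and 2.43%). These lie farther from the J segments than TRAV17 to TRAV21, so the list does not measure nearness to the J segments. TRAV12 made up 2.07% ± 0.124 and 3.53% ± 0.238 (4 of 7 lower, 1 higher), TRAV9 0.173% ± 0.0303 and 0.215% ± 0.0359 (2 of 5 lower, 1 higher), and TRAV1 with TRAV2 0.687% ± 0.110 and 1.23% ± 0.114 (2 of 2 lower). The 3' J segments made up 39.7% ± 1.56 and 33.0% ± 0.276, with 5 higher and 6 lower of 14, and the 5' J segments 14.3% ± 0.698 and 16.1% ± 0.767, with 5 higher and 5 lower of 13. Except for the TRAV16 to TRAV21 list, the counts were the same when adjusted over the list alone. By fry the adjusted p was 5.52e-06 for TRAV14, 2.59e-05 for TRAV4, 8.8e-06 for the TRAV16 to TRAV21 list, 3.98e-05 for TRAV12, 0.0178 for TRAV9, 0.000985 for the 3' and 0.00313 for the 5' J segments. None of these passed with camera, where the adjusted p ran from 0.226 to 0.938 with an estimated correlation. The J lists had medians of -0.08 and 0.14 against means of 0.11 and -0.13, so median and test differed in sign. Without the invariant chain, which carries the 3' segment TRAJ18, the 3' J segments made up 35.3% ± 1.01 and 32.9% ± 0.282 (fry adjusted p = 0.00502). The 5' J segments then made up 15.3% ± 0.617 and 16.1% ± 0.767 and did not pass (fry adjusted p = 0.123), nor did they with TMM factors and the chain kept (fry adjusted p = 0.1227).

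Residues at the CDR3 middle differed between the lineages. In TRA, aspartate 1 residue before the middle made up 4.48% ± 0.261 in CD4SP and 10.98% ± 0.318 in CD8SP (log2 fold change -1.297, SE 0.029, n = 6), and glutamate 2 residues before it 4.87% ± 0.259 and 8.68% ± 0.261 (-0.84). Arginine 2 residues before the middle (1.19) and glutamine 1 residue before it (0.88) were higher in CD4SP, and without the invariant chain, which carries that arginine, they were at 0.48 and 0.98. In TRB, glutamine 2 residues before the middle was higher in CD4SP (0.93) and phenylalanine there lower (-0.75), and arginine at the middle was lower (-0.24). The net charge of the inner CDR3 was 0.751 ± 0.00923 in CD4SP and 0.431 ± 0.00685 in CD8SP for TRA, and -0.757 ± 0.00702 and -0.854 ± 0.00855 for TRB. Without the invariant chain the TRA values were 0.733 ± 0.0109 and 0.431 ± 0.00682. Cysteine at the TRB middle made up 0.0108% ± 0.00290 and 0.0262% ± 0.00836 (-1.26, SE 0.469, edgeR adjusted p = 0.0134). edgeR called 68 of 94 TRA residues (26 higher and 42 lower) and 65 of 100 TRB residues (30 and 35), and DESeq2 called 29 and 31, and 32 and 30. At the other TRB offsets cysteine did not pass (adjusted p from 0.0634 to 0.631), nor in TRA (0.57 and adjusted p = 0.186 at 1 residue before the middle, -0.26 and adjusted p = 0.431 at 2 before). The cysteine call ended without WT mouse 2 (adjusted p = 0.0597), without knockout mouse 3 (0.0524) and with each clonotype counted once (0.0941).

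Of the 27 measures, 17 went one way in 6 of 6 mice, 10 higher and 7 lower in CD4SP, each with an exact sign-flip permutation p = 0.031, the smallest that 6 mice allow, and an adjusted p = 0.0496. Among them, out-of-frame or stop reads made up 2.16% ± 0.139 of CD4SP and 1.42% ± 0.0555 of CD8SP TRB reads. Nucleotides between V and J numbered 1.71 ± 0.0209 and 1.81 ± 0.0107 in TRA and 8.86 ± 0.0337 and 8.99 ± 0.0354 in TRB. The 100 largest TRA clonotypes held 12.1% ± 1.15 and 6.85% ± 0.345 of reads, but 6.30% ± 0.335 and 6.89% ± 0.342 without the invariant chain, which turned the direction. Without that chain the TRA nucleotides between V and J were 1.803 ± 0.0247 and 1.81 ± 0.0105 and no longer went one way in 6 of 6 mice. CD4SP had 42326 ± 1346 distinct TRB clonotypes against 36811 ± 1477 in CD8SP at 74021 reads, which cannot be set apart from the larger number of CD4SP cells sorted. Of public clonotypes, 168 of 286 TRA (77 higher and 91 lower in CD4SP) and 119 of 203 TRB (76 and 43) passed. The invariant chain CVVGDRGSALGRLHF was at 6.29% ± 1.076 and 0.0433% ± 0.00990 (log2 fold change 7.18, SE 0.165). The TRAV16N and TRAJ22 join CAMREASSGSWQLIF was lower in CD4SP, at 0.0198% ± 0.0103 and 0.219% ± 0.0405. Among beta chains, the TRBV31 chain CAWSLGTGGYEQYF was higher (0.0349% ± 0.0187 and 0.00132% ± 0.00211) and the TRBV14 chain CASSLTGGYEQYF lower (0.00222% ± 0.00182 and 0.0222% ± 0.00699).

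CD4SP and CD8SP libraries with the same genotype and number shared more TRB clonotypes than CD4SP and CD8SP libraries of different mice. The share of distinct TRB nucleotide clonotypes in common (Jaccard index, at equal reads, and for TRA without the invariant chain) was 1.54% (1.47% to 1.61%, n = 6) within a mouse and 0.821% (0.745% to 0.877%, 30 library pairs) between mice. For TRA it was 3.54% (3.29% to 3.76%) and 3.50% (2.96% to 4.03%). In another single draw of reads, the TRB excess within a mouse was 0.730 ± 0.0455 percentage points (SD over 6 mice). Of the 720 ways to pair the 6 CD4SP with the 6 CD8SP libraries, 1 gave an excess as large, the real one (exact p = 0.00139). The TRA excess was 0.00904 ± 0.119 (exact p = 0.390). That test was chosen after the values were seen. Within 1 cell type, sharing between libraries of the same genotype minus that between genotypes was 0.0155 percentage points for TRA in CD4SP, -0.0832 for TRA in CD8SP, 0.0152 for TRB in CD4SP and 0.00232 for TRB in CD8SP. The exact p over the 10 splits of 6 libraries ran from 0.2 to 0.9, and as 0.1 is the smallest possible, these splits cannot show or exclude a genotype effect on sharing.

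**Figure D3:**
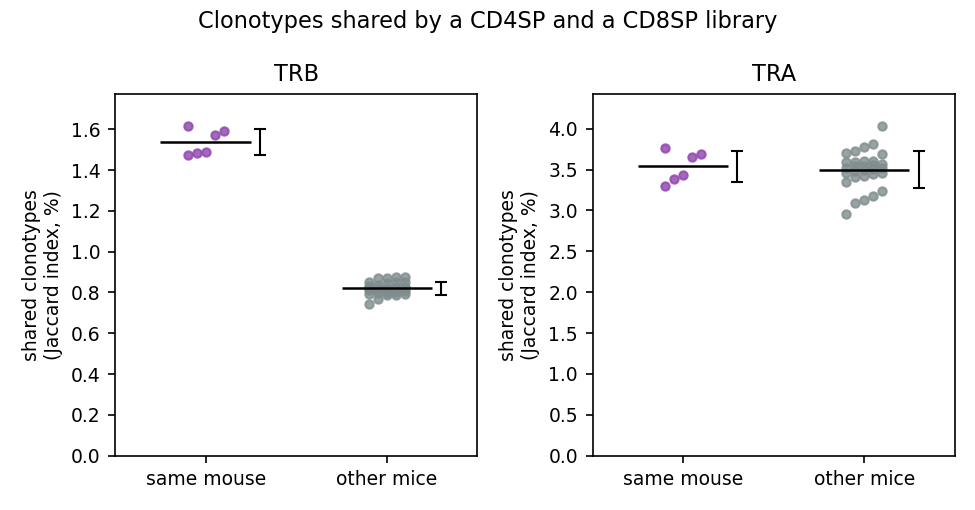
Jaccard index (%) of nucleotide clonotypes between a CD4SP and a CD8SP library, as points for pairs of libraries from the same mouse (6) and from different mice (30), with the mean and SD, for TRB and TRA on separate axes. The TRB values of the same mouse, 1.47% to 1.61%, lay above all values between mice.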

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

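Of the tests here, the invariant chain without its most read sequence, the merged TRAV11 copies, the CDR3 length without the invariant chain and both tests of the TRD reads were chosen only after the results were seen; the test of the NKT partner beta chains was chosen after the invariant chain result was seen and the single TRB segments had been tested, but written before the summed share was computed.

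The invariant NKT chain was more abundant in knockout than in WT CD4SP libraries by 1.35 ± 0.530 percentage points, in 3 of 3 pairs. Amplification of a single sequence was excluded, since without the most read sequence the difference was 0.747 ± 0.216, in 3 of 3 pairs, and 4 nucleotide sequences of the same chain, 92.4% of the invariant reads, were each higher in 3 of 3 pairs. Reads split between TRAV11 copies were excluded too, as TRAV11 with its copies merged rose by 0.24 (SE 0.057, edgeR adjusted p = 0.00101). A higher number of NKT cells in the knockout sorts may be the source. The beta chains that pair with the chain (TRBV13-2, TRBV29 and TRBV1) differed by -0.0377 ± 0.951 percentage points, a wide spread. Their sum cannot decide this, as it does not follow the chain. In WT it was 11.3% ± 0.592 in CD4SP and 16.1% ± 0.475 in CD8SP, where the chain made up only 0.0708% of TRA reads. TRBV13-2 alone, the main partner, differed by 0.0333 ± 0.226, higher in 1 of 3 pairs. How far more NKT cells would raise it was not measured. NKT cells that hold more receptor RNA per cell also cannot be told apart from more NKT cells. Leaving out WT replicate 1, WT replicate 3 or knockout replicate 3 left TRAV11 at log2 fold changes of 0.24, 0.21 and 0.21, near the 0.25 of all libraries, but ended the calls (adjusted p = 0.0565, 0.154 and 0.229), and knockout replicate 3, with the fewest productive TRA reads of its group (23765), had the highest share (8.49%, 95% Wilson interval 8.14% to 8.85%).

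Reads of TRDV or TRDJ segments appeared in data that the genotype tests of segments did not use, above the level that 3 reads would give (0.00788% to 0.0135% of a library's TRA and TRD reads). They made up 1.04%, 1.02% and 1.04% in WT CD4SP replicates 1 to 3 and 0.892%, 0.798% and 0.877% in knockout CD4SP. In CD8SP they made up 1.16%, 0.861% and 0.972% in WT and 0.744%, 0.839% and 0.686% in the knockout. The share was lower in 3 of 3 pairs in each cell type, with groups that did not overlap (exact label permutation p = 0.1, the smallest possible, n = 3). Fewer chains with a TRDJ segment were excluded as the source of the lower share, since at most 1.29% of a library's TRD reads held one. With so few in any library, the number of gamma-delta cells in the sorts cannot be read from these data. The other TRD reads joined a TRDV segment to TRAJ, as alpha chains can. Whether these reads were assigned to the right V segment was not tested. TRDV1, singled out after its values were seen because it held 81.1% to 96.6% of these reads, was at -0.33 (SE 0.124, edgeR adjusted p = 0.247) in CD4SP and at -0.40 (SE 0.125, adjusted p = 0.0849) in CD8SP. Longer recombination of the alpha locus, in which later V to J joins delete earlier ones, might lower the share. The mean TRAJ number differed by -0.261 ± 0.369 over 6 pairs of libraries, which leaves it open. These came from 3 pairs of mice in 2 cell types, so the 6 are not independent.

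The knockout effect on TRA CDR3 length went opposite ways in the cell types, at 0.0522 nucleotides in CD4SP (3 of 3 pairs higher) and -0.0667 in CD8SP (3 of 3 lower), on means of 40.2 and 40.5 in WT. The difference of 0.119 ± 0.0302 had an exact sign-flip permutation p = 0.25 over 3 pairs, the smallest possible. The invariant chain is longer than the mean, and without it the effect was -0.0189 in CD4SP and -0.0662 in CD8SP, lower in 3 of 3 pairs in each, so the opposite directions ended. The knockout effect on the net charge of the inner TRB CDR3 also went opposite ways, at 0.00867 in CD4SP and -0.0119 in CD8SP. Its difference was 0.0206 ± 0.00952, with the same exact sign-flip permutation p = 0.25.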

How the results depend on the processing

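Alternatives that leave out the invariant chain, merge TRAV copies or add TRDV segments were chosen only after the result was seen; the others were set in advance. Of 2093 alternative values for 159 named features and shares, 1937 kept direction and side of the threshold, and 51 lost and 15 gained a call. In 82 the sign changed where the main fit had no call, and in 8 it changed where the main fit had a call. For the values below the cause was not tested, except where fewer features or libraries are named as the reason. Counting clonotypes once or leaving out the invariant chain takes away that chain's read abundance. A call that rests on it is then lost by design.

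In knockout against WT CD4SP, the 2 TRA segment calls became 0 with each clonotype counted once (TRAV11 -0.13, TRAJ18 -0.0210), 0 without tied segments (TRAV11 is then removed) and 0 without the invariant chain (TRAV11 -0.16), 1 with DESeq2, and 0 to 3 with 1 library left out: 0 without WT replicate 1, WT replicate 3 or knockout replicate 3. The 6 TRA residue calls became 0 with clonotypes counted once (alanine -0.0181), 0 with DESeq2, 0 without the invariant chain (alanine -0.0197, leucine 0.14, asparagine -0.12), 1 without clonotypes of 1 read, and 1 to 7 with 1 library left out: 1 without WT replicate 1 and 2 without knockout replicate 3. Counts of 0 became 1 for TRA public clonotypes with DESeq2 and without knockout replicate 2 (range 0 to 1), for TRB segments (TRBJ2-7) without clonotypes of 1 read, with only the 6 libraries, and without WT or knockout replicate 3 (range 0 to 1), and for TRB residues with clonotypes counted once and without WT replicate 1 (range 0 to 1). In CD8SP, 0 became 1 for TRA segments with TMM (TRAV14D-1), 1 for TRB public clonotypes without clonotypes of 1 read, and 3 for TRB segments without WT replicate 2 (range 0 to 3). In the test of different effects, TRB segments went from 0 to 2 without WT mouse 2 (range 0 to 2).

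Without the replicate block the 2 TRA segment calls in CD4SP became 0 (adjusted p = 0.0822 for both), and measures whose groups do not overlap numbered 4 in CD4SP and 4 in CD8SP, against 13 and 7 measures of one direction in all pairs. Same-numbered WT and knockout libraries deviated together weakly (mean correlation over segments 0.162 for TRA, over 0.1 in 3 of 6; -0.0156 for TRB, 2 of 6), so the data do not show that the numbers pair the mice. By the methods' paired test 6 CD4SP and 0 CD8SP measures passed unadjusted, and 0 and 0 adjusted. With a pair left out, the count was 17 to 19 in CD4SP and 9 to 21 in CD8SP (21 without replicate 1, 11 without replicate 2), where 2 pairs give 13.5 by chance.

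Between CD4SP and CD8SP, TRAV11 went from 3.01 to -0.0645 with clonotypes counted once and -0.23 without the invariant chain, TRBV15 from 0.13 to -0.0266 with DESeq2, and the 9 lists past the threshold became 0 with camera, which both estimates the correlation and compares with the other segments. DESeq2 moved the median log2 fold change by 0.12 for TRA segments, 0.14 for TRA residues and 0.36 for TRB public clonotypes, and TMM moved that of TRB segments by -0.13 (16 higher, 16 lower). Between genotypes DESeq2 moved public clonotypes by 0.16 (TRA, CD4SP), -0.11 (TRA, CD8SP) and 0.22 (TRB, CD8SP). Public clonotypes could not be refitted with clonotypes counted once, which left no feature. In simulation, 0% of their 2-fold genotype changes were recovered.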

Other observations

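The tests of CD4SP cells in the CD8SP sorts, of the mouse level and of other splits of the libraries were chosen only after the results were seen; the tests of long alpha joins and of out-of-frame beta chains were written before their values were seen, but after the sharing of all clonotypes was. The test of long alpha joins was written for cells or reads mixed into a library and narrowed to reads after its value was seen, because a mixed cell need not share its alpha chain with a sampled cell.

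The MAIT chain, the only other invariant receptor counted, made up 0.0175% ± 0.00899 of CD4SP and 0.0144% ± 0.0108 of CD8SP productive TRA reads (n = 6). The main invariant NKT protein, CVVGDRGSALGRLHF, was encoded by 9 distinct nucleotide sequences over the CD4SP libraries, of which the most read held 42.8% of its reads and the next 25.1%. Its variants included, the invariant chain had 38 sequences. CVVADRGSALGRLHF and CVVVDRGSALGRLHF, which differ at 1 residue of the join, made up 0.198% and 0.160% of CD4SP reads and had 0 reads in CD8SP. Beta chains had 1.055 ± 0.00137 nucleotide clonotypes per amino acid clonotype in CD4SP against 1.045 ± 0.00192 in CD8SP, higher in 6 of 6 mice, which cannot be set apart from the larger number of CD4SP cells sorted.

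TRB clonotypes were shared by the CD4SP and CD8SP libraries of 1 mouse in excess, by 0.730 ± 0.0455 percentage points in 6 of 6 mice. Reads of the mouse's other library mixed into a library would carry alpha chains too, but alpha clonotypes with at least 4 nucleotides between V and J had an excess of 0.0333 ± 0.0815 (exact p = 0.146). CD4SP cells in the CD8SP sorts were bounded by the invariant chain there: the excess needed 1.53% of CD8SP clonotypes, the bound averaged 1.01%, and the difference was 0.516 ± 0.447, above 0 in 5 of 6 mice (WT mouse 1 was at -0.321). A candidate explanation is beta clones that divided before the lineages parted, and would then share out-of-frame joins of the other allele; that excess was 0.0445 ± 0.0478 (5 of 6 mice, exact p = 0.0361), with a median of 1 shared clonotype, too few to decide. This stays a hypothesis.

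Segment usage may carry a level of the individual mouse. Deviations of 33 TRB segments from their group means went together in CD4SP and CD8SP of the same mouse. Of the 720 pairings of the libraries, 2 gave as large a mean product, the real one included (permutation p = 0.00278). For 73 TRA segments 7 of 720 did (permutation p = 0.00972). As the means were taken within genotype, pairings across genotypes are not fully exchangeable, so both p-values are approximate and may be too small. For TRA, same-numbered WT and knockout libraries had the same mean correlation of deviations as libraries of 1 mouse (0.162 for both). A level of the replicate number cannot be set apart there. For TRB the values were -0.0156 and 0.410. A difference in alleles was looked for in the V segments' differences from the reference. Of 34705 seen, of any read count, 1 differed strongly between libraries and was not followed up. Libraries with under 30 reads of a segment counted as lacking a difference, so this check does not settle whether alleles differed. Littermate or founder origin, age and sex of each mouse were not given in the sources used here and stay open.

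Splits of the 6 libraries of a cell type into other groups of 3 were too few, at 10, for a share under 0.05. In CD4SP the real split gave 2 TRA segments against at most 1 in another split, and 6 TRA residues against at most 1, so 1 split of 10 was as large in each. It gave 0 TRA public clonotypes (highest other 1), 0 TRB segments (0), 0 TRB residues (1) and 0 TRB public clonotypes (0). In CD8SP it gave 0 TRA segments (0), 0 TRA residues (0), 0 TRA public clonotypes (0), 0 TRB segments (2), 0 TRB residues (0) and 0 TRB public clonotypes (0), and for different effects 0 TRA segments (1) and 0 TRB segments (4); in all results of 0, each of the 10 splits was at least as large. Between CD4SP and CD8SP, 1 of 32 swaps within mice, the real one, was as large for TRA segments (98, highest other 0), TRA residues (68, 0), TRA public clonotypes (168, 0), TRB segments (30, 0), TRB residues (65, 0) and TRB public clonotypes (119, 5), so an arbitrary grouping of the libraries is excluded there at that share.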
